A study of Saccharomyces cerevisiae with 54 samples.

How the data were processed

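Gene expression was measured in budding yeast of the SK1 background in exponential growth and in sporulation medium. The assays were ribosome profiling, mRNA sequencing and total RNA sequencing, and a strain with inducible Ndt80 was measured by mRNA sequencing. The series holds 54 samples, and 52 libraries were used. The submitters' processing notes name CASAVA and bcl2fastq 2.17 for demultiplexing and Bowtie2 for alignment, with no versions for CASAVA and Bowtie2. The counting tool, the genome build, the annotation and the strand counted are not given in the sources used here, so no coordinates are printed.

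Per the file headers, values are RPKM (reads scaled by gene length and by library total), computed by the authors, with 1 column per library in 5 tables of 6679 genes each. What the total in their denominator was counted over is not given in the sources used here. Genes are listed by systematic name. A yeast reference was used for symbols only and holds 5994 of the genes. The other unit is that of 9 of the 10 deposited total RNA columns, headed RPKM, whose values behave as reads multiplied by length where RPKM divides by it. All 10 were put on one scale, reads per length and per total of the library. The vegetative total RNA column had been deposited on the RPKM scale, and its list changes against 0 h are not given singly. In the deposited table of the induction series, the line under the header holds hours and was not read as a gene.

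Recovered reads were the RPKM values times the reference length less 60 bases over the value of 1 read, and a value up to 100 counted as whole within 0.02. The share of whole values was 78.1 to 90.7% over libraries. Depth limits low values most in the parallel footprint libraries of 0 h (1.03 in units of 1000000 reads) and of 6 h replicate 2 (1.41). In the table of the parallel libraries, 443 genes, 375 of them with a reference entry, were listed in another order than their names in 11 libraries. Their values were assigned by position, under which whole reads were recovered and the values correlated with the course, and the vegetative and 0 h footprint columns were assigned by name. The 2 mRNA columns for 3 h were identical in all genes and entered as 1 library. The parallel mRNA sample of 0 h was not used here because its column could not be assigned. In all, 6 per-sample columns were not used, and 5 lines without a gene name were left out.

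Values were log2(RPKM + 1). Genes with a mean of at least 5 RPKM over the libraries of a fit were tested with limma 3.58.1 (R 4.3.3), with a trended eBayes prior and Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. The parallel fit held 11 libraries with 5 residual degrees of freedom and a prior of 3.97, after 12 libraries had been planned. It gave mRNA and footprint changes of 3 h against 1.5 h and 6 h against 3 h, and translation efficiency as the interaction of assay and time, that is, the footprint change minus the mRNA change. The lone 3 h mRNA library is assumed to vary like the other groups. Genes called in both assays with opposite signs were counted as opposed. The induction fit held 9 libraries with hour as a linear term, 6 residual degrees of freedom and a prior of 4.3. Counts for independent lists are the products of the shares of called genes times the genes tested. The 10 states of the course have 1 library per assay and were described without a test. Course changes of a list were set against 10000 random lists of the same size, matched on expression in 20 bins, and the central 95% was used. Course changes against 0 h are relative to the all-gene median because the 0 h mRNA library has another scale. All other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

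The 20 gene lists, written from general knowledge, were early meiotic and recombination genes, middle meiotic genes of the Ndt80 regulon, spore wall and late genes, monopolin and meiotic cohesion genes, kinetochore genes, mitotic and G1 cyclin genes, a-specific and haploid-specific genes, histone genes, DNA replication genes, cytosolic ribosomal protein genes, ribosome biogenesis genes, glycolysis and fermentation genes, gluconeogenesis, glyoxylate and acetate use genes, TCA cycle genes, respiratory chain and ATP synthase genes, proteasome genes, chaperone and stress genes, autophagy genes, genes with reported long undecoded transcript isoforms and genes reported as targets of Rim4. Some genes are in more than 1 list, and all Rim4 targets are also in the middle list. Members of the last 2 lists may have been reported from these samples. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over lists. A list of 7 galactose genes was written after GAL2 and GAL7 were seen to pass.

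Named genes followed a rule. For each contrast they were the 6 largest rises and 6 largest falls among called genes with a standard symbol. The groups' libraries did not overlap for these genes. Added to them were up to 4 members per described list with the smallest adjusted p. Up to 6 opposed genes per direction were taken, those with the largest difference between footprint and mRNA change. NDT80, IME1, NDC80, CLB3 and the members of the long-isoform and Rim4 lists were always eligible. In the course the rule took up to 3 members per list with the largest range and the 6 genes with the largest range of translation efficiency among genes with at least 20 RPKM in both assays. Genes of paralog families such as SSA2, SSA3, HXT10, AAD3, AAD6, COS6, histones and ribosomal proteins may share reads. The values of 1 gene of the cyclin list are not reported here.

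The procedure was tested on simulated data with 100 changed genes per size. At a true log2 change of 1 it recovered 23% of genes in mRNA and 56% in footprints between 1.5 and 3 h, 38% and 51% between 3 and 6 h, 18% and 8% in translation efficiency, and 0% in the induction fit. At a true change of 2 these shares were 77, 89, 81, 82, 56, 53 and 33%. In the induction fit the simulated change was the same in all induced libraries. The shares there do not describe the recovery of a change that grows with time after induction. Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, a minimum mean of 20 RPKM or none, median centring, quantile normalization, no trend, a doubling or halving, replicate number as a block, course libraries added, a separate fit per assay, leaving out each library, other subsets of the induction series and an estimated correlation for lists. Alternatives added after the data were seen were voom on recovered reads, leaving out the genes listed out of order, list tests on centred values and the overlap of the late induction comparison with the wild type.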

Results

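Budding yeast of the SK1 background were sampled during exponential growth, at 0, 1.5, 3, 4.5, 6, 8 and 10 h in sporulation medium, and as spores. The course has 10 states, each with 1 ribosome footprint library, 1 mRNA library and 1 total RNA library. The headers of its vegetative mRNA and total RNA columns name replicate 1, and those of its other states name no replicate. Whether the growing cells belong to the same series of samples is therefore not settled. Its last state is a MATa/a strain at 4.5 h, a diploid that carries only the a mating type and therefore does not enter meiosis. A parallel set holds 2 footprint libraries each at 1.5, 3 and 6 h, 1 each from growing cells and 0 h, and 2 mRNA libraries each at 1.5 and 6 h. Its 2 mRNA columns for 3 h were identical in all 6679 genes and were counted as 1 library. A further 9 mRNA libraries come from a strain in which the transcription factor Ndt80 can be induced, 4 uninduced (4, 5.5, 6 and 7.75 h) and 5 induced (5.75, 6, 6.5, 7 and 7.75 h). In all, 52 libraries were used. Footprints are the mRNA fragments protected by ribosomes, and translation efficiency is the log2 footprint value minus the log2 mRNA value of a gene. The reads recovered from the deposited values ranged, in units of 1000000 reads, from 2.62 to 8.02 in the induction libraries and from 1.03 to 17.7 in the parallel libraries. They ranged from 2.28 to 17.0 in the course footprints, from 8.70 to 24.7 in the course mRNA and from 1.63 to 6.93 in the course total RNA. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene lists, the rule for naming genes, the tests and most alternatives were chosen before the data were examined.

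The series asks how far transcript levels and translation move together through meiosis. In the course, genes of successive meiotic stages were higher in successive libraries. Relative to all genes, the median mRNA of 36 early meiotic and recombination genes stood 3.99 above its 0 h value on the log2 scale at 1.5 h, 4.67 at 3 h and 2.56 at 8 h. GMC2, which acts in synaptonemal complex assembly, had 209 RPKM at 1.5 h and 1294 at 3 h, and MEI5, a recombination factor, 952 and 2478. The 37 middle genes of the Ndt80 regulon stood 1.83 above 0 h at 3 h, 6.71 at 4.5 h and 7.29 at 8 h. SPS4, a sporulation gene, had 470 RPKM of mRNA at 3 h, 41910 at 4.5 h and 180800 at 8 h. NDT80 itself had 201 RPKM at 3 h and 2251 at 4.5 h. The 19 spore wall and late genes stood 2.10 above 0 h at 3 h, 4.42 at 4.5 h and 8.16 at 8 h. Each of these medians lay at the 100th percentile of 10000 random lists matched on size and mean expression. IME1, the master regulator of entry into meiosis, had 3831 RPKM at 1.5 h and 351 at 8 h.

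Genes of DNA synthesis were high early in the course. Histone mRNA stood 2.90 above 0 h at 1.5 h (percentile 100) and 1.31 at 8 h, inside the central 95% of random lists. The 34 DNA replication genes stood 2.49 above 0 h at 1.5 h (percentile 100) and 0.53 at 8 h, inside that range. RNR1, the large subunit of ribonucleotide reductase, had 1366 RPKM at 1.5 h and 90.5 at 6 h. Metabolic and ribosomal protein genes also differed from 0 h. Genes for gluconeogenesis, the glyoxylate cycle and acetate use stood lower in growing cells than at 0 h (median -7.67, percentile 0), and the 137 ribosomal protein genes stood 3.75 above (percentile 100). The vegetative mRNA column carries a replicate mark that the other states lack, so a difference between sample series is not excluded. Glycolysis genes had a median of -3.70 at 1.5 h (percentile 0). Ribosomal protein mRNA stood 2.28 above 0 h in spores (percentile 100).

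Translation efficiency in the course was low at some times for the following lists. Relative to all genes and to 0 h, the 6 genes reported as targets of the translational repressor Rim4 had a median of -1.84 at 3 h (percentile 0.01) and -0.55 at 6 h (percentile 9.44). Translation efficiency of CLB3, a B-type cyclin of the second meiotic division, relative to all genes was -3.37 at 1.5 h and 0.20 at 6 h. The 5 genes with reported long undecoded transcript isoforms, 5'-extended mRNAs that do not yield the protein, had a median of -1.97 at 4.5 h (percentile 0.06). Translation efficiency of NDC80, a kinetochore subunit, relative to all genes was -0.21 at 0 h and -2.18 at 4.5 h. Ribosomal protein genes had a median of -1.55 at 6 h (percentile 0). Of the 6 genes with the largest range of translation efficiency, ALD3, an aldehyde dehydrogenase, had 5.22 RPKM of footprints at 8 h and 1140 at 10 h. The course has no replicates and no test. The 0 h mRNA library is on another scale, with 8.33 recovered reads per read of its denominator, against 2.96 to 3.58 in the other course mRNA libraries, and the median gene stood at -0.56 to -1.32 in mRNA against 0 h. Course changes against 0 h are therefore given relative to all genes, and RPKM of single mRNAs only at other times.

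**Figure D1:**
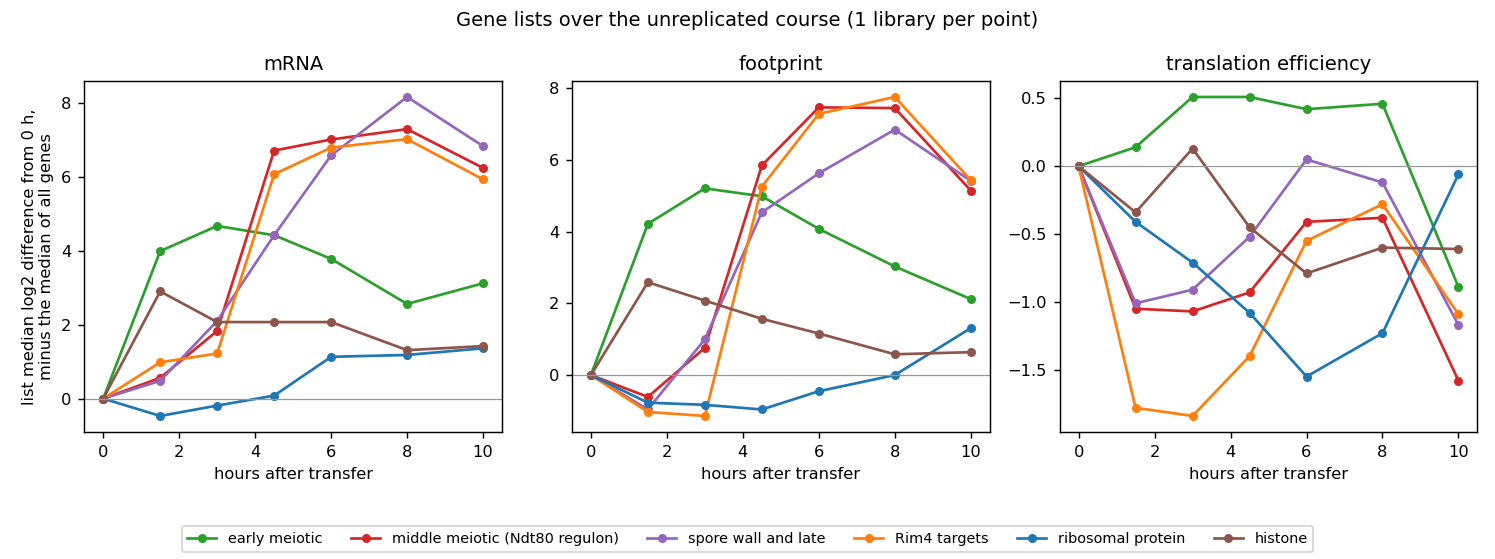
Median log2 mRNA, footprint and translation efficiency values of 6 gene lists relative to 0 h and to all genes (vertical axes, log2) against hours after transfer to sporulation medium (horizontal axis), 1 library per point. The early list leads at 1.5 h, and the middle list stands 6.71 above 0 h at 4.5 h in mRNA.

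The course held 720 medians of lists, those of vegetative total RNA against 0 h included. Of these, 247 lay above and 189 below the central 95% of matched random lists. In simulated data without change, where genes varied independently, 1 of 40 lists lay outside it. Members of real lists can vary together, so this share does not carry over to them. Over genes, the changes in the course and in the parallel libraries correlated with Pearson's r of 0.92 for mRNA, 0.91 for footprints and 0.58 for translation efficiency between 3 and 6 h. Between 1.5 and 3 h r was 0.71, 0.65 and 0.43, and the median of the 6 values was 0.68. Genes are not independent replicates. The mRNA and total RNA libraries of one state correlated over 5606 genes with r from 0.83 to 0.92 (median 0.85). The median ribosomal protein gene was 1.99 to 2.81 higher in mRNA than in total RNA, relative to all genes, in 9 states. In growing cells it was 0.57 higher. All total RNA values were on one scale here, and the cause of the difference was not tested.

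The MATa/a strain tests which changes need meiosis. The footprint library labelled MATa/a 4.5 h lacked the meiotic programme. Relative to all genes and to meiotic cells at 4.5 h, its early genes had a median of -6.00, its middle genes -6.28 and its spore wall genes -5.25, while genes for gluconeogenesis and acetate use stood at 0.29. The mRNA library labelled MATa/a 4.5 h instead resembled growing cells. It correlated with the vegetative mRNA library at r = 0.97 across genes, with the spore library at 0.76 and with the meiotic 4.5 h library at 0.54. Its gluconeogenesis list had a median of -5.66 and its ribosomal protein list of 4.70. The total RNA library with this label correlated with the vegetative one at 0.95. The following genes were chosen after their values were seen. PCK1, the gluconeogenic carboxykinase, had 30.7 RPKM of mRNA and 565 of footprints. ADH2, the glucose-repressed alcohol dehydrogenase, had 286 of mRNA and 109300 of footprints. ICL1, isocitrate lyase, had 75.4 and 6010, and the ribosomal protein gene RPL3 had 18177 and 2788. The labelled genotype could be read only in part. STE2, the a-cell pheromone receptor that a/alpha cells turn off, had 488 RPKM of mRNA in the MATa/a library and 58.1 in the meiotic 4.5 h library, but also 568 in the library labelled vegetative. STE3, the receptor of alpha cells, had 0.825, 135 and 1.43 in the same libraries. The mating type of the library labelled vegetative is therefore not settled here, and growth medium is not shown to be its only difference from 0 h. The mRNA and footprint libraries of this state correlated most with different states, which limits any translation efficiency computed from them.

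**Figure D2:**
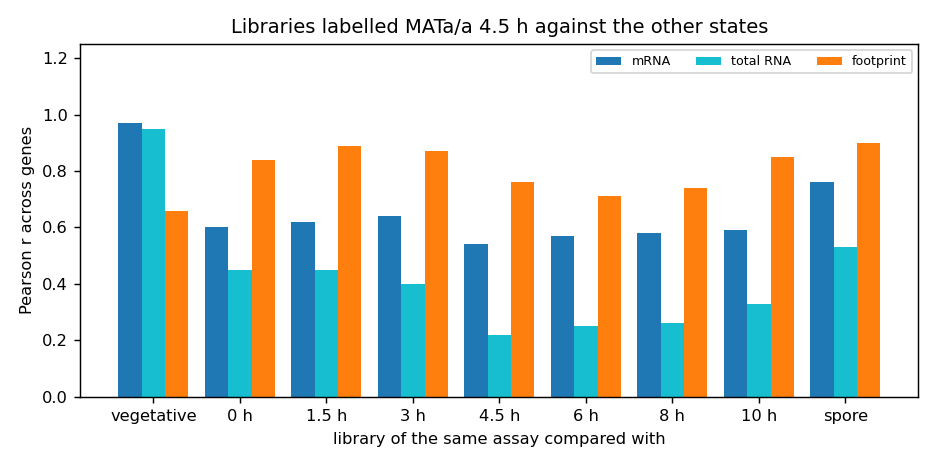
Pearson correlation across genes (vertical axis) of the libraries labelled MATa/a 4.5 h with the other states of the course (horizontal axis), by assay. The mRNA library correlates most with vegetative cells (0.97), and the footprint library with spores (0.90) and 1.5 h (0.89).

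Between 1.5 and 3 h the parallel libraries ask what changes while cells go from premeiotic S phase into recombination. The mRNA of some meiotic genes rose. LDS1 (YAL018C) and LDS2, which act in lipid droplet and spore wall formation, rose by 3.15 (SE 0.260, limma, adjusted p = 0.00149) and 3.13 (SE 0.323, adjusted p = 0.00319) on the log2 scale. NDT80 (YHR124W), the activator of the middle genes, rose by 2.84 (SE 0.218, adjusted p = 0.00118). GMC2 rose by 2.87 (SE 0.380), MAM1, a monopolin subunit, by 2.80 (SE 0.301) and PRM6, a potassium transporter, by 2.78 (SE 0.506). The largest falls were MET6, methionine synthase, with -2.18 (SE 0.479), ARG56, of arginine synthesis, with -2.04 (SE 0.327), and FLO11, a cell wall adhesin, with -1.85 (SE 0.397). BAP2, an amino acid permease, had -1.84 (SE 0.402), SUC2, invertase, -1.67 (SE 0.220) and DPM1, of dolichol mannose synthesis, -1.58 (SE 0.257). IME1 (-0.22, adjusted p = 0.752), NDC80 (0.64, adjusted p = 0.336) and CLB3 (-0.16, adjusted p = 0.774) did not pass the test.

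By list, 6 of 36 early genes rose, among them SAE3 (1.52), SPO11 (1.48), which cuts DNA to start recombination, and ZIP1 (1.30), and 30 did not pass; adjusted over the list alone, 17 rose. The list call (camera, adjusted p = 5.03e-09) was lost, with adjusted p = 0.369 with an estimated correlation. Of 37 middle genes 15 rose, with SPR28 at 2.27 and IRC18 at 1.92, and adjusted over the list alone 24 rose and 1 fell (adjusted p = 0.0666 with an estimated correlation). Of 19 spore wall genes 7 rose, with CDA1, chitin deacetylase, at 2.29 and DTR1 at 1.99, and adjusted over the list alone 10 did (adjusted p = 0.137 with an estimated correlation). Of 10 histone genes 6 fell, with HTB1 at -1.28 and HTB2 at -1.40, and adjusted over the list alone 7 fell and 1 rose (adjusted p = 0.336 with an estimated correlation). Of 34 DNA replication genes 7 fell, with the primase subunit PRI2 at -1.29 and RNR1 at -1.56, and adjusted over the list alone 12 did (adjusted p = 0.336 with an estimated correlation). Of 33 proteasome genes 8 rose, with RPN13 at 1.27 and PRE10 at 1.02, and adjusted over the list alone 23 did (adjusted p = 0.354 with an estimated correlation). Of 28 chaperone and stress genes 5 rose, with SSA3 at 1.18 and HSP78 at 1.00, and adjusted over the list alone 13 did (adjusted p = 0.369 with an estimated correlation). With each library centred on its median, 1 proteasome and 1 chaperone gene rose. In the monopolin list 1 of 8 genes rose, MAM1, and 3 did adjusted over the list alone (adjusted p = 0.406 with an estimated correlation). In the kinetochore list 2 of 27 rose, SPC19 (1.15) and DAD4 (1.60), and 8 did adjusted over the list alone. In the TCA cycle list 1 of 15 fell, ACO1, aconitase (-0.95), also adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). HNT1 (1.00) was the 1 of 5 genes with reported long isoforms to rise, and SPO20 (1.23) and SSP1 (1.41) the 2 of 6 Rim4 targets, with the same counts adjusted over the list alone. No gene of the other lists passed, namely 10 cyclin, 16 a-specific and haploid-specific, 137 ribosomal protein, 63 ribosome biogenesis, 18 glycolysis, 15 gluconeogenesis, 31 respiratory and 29 autophagy genes. Adjusted over the list alone, 2 a-specific and haploid-specific genes rose. Ribosomal protein and glycolysis genes stood lower than others as lists, with adjusted p = 0.816 and adjusted p = 0.597 with an estimated correlation. The ribosomal protein median relative to all genes, -0.15, turned to 0.31 without mRNA 1.5 h replicate 1 (camera at the preset correlation, adjusted p = 0.000461).

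Over all 5967 genes tested, 181 mRNAs rose and 48 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and the median gene changed by 0.11. Centring gave 87 up and 62 down, and quantile normalization 126 up and 132 down. The total of 229 was 69 and 68 without footprint 3 h replicate 1 or 2, 61 without either footprint 6 h replicate, and 102 and 129 without mRNA 1.5 h replicate 1 or 2.

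Footprints of some of these genes rose as well. LDS1 rose by 3.80 (SE 0.213, adjusted p = 3.78e-05), LDS2 by 3.65 (SE 0.264), SMK1, a sporulation kinase, by 3.61 (SE 0.221) and NDT80 by 3.54 (SE 0.178, adjusted p = 3.08e-05). The septin SPR3 rose by 3.25 (SE 0.219) and PFS1 by 3.24 (SE 0.273). The largest falls were HHY1 (-3.44, SE 0.564), DAL7 (-2.60, SE 0.619), a malate synthase of allantoin use, the aldehyde dehydrogenase ALD5 (-2.56, SE 0.597), the chitinase CTS1 (-2.43, SE 0.569), ARG8 (-2.41, SE 0.318), of ornithine synthesis, and the carrier OAC1 (-2.38, SE 0.552). IME1 (0.38, adjusted p = 0.365), NDC80 (-0.08, adjusted p = 0.899) and CLB3 (-0.49, adjusted p = 0.163) did not pass.

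By list, 18 of 36 early genes rose, with GMC2 at 3.14, and 29 did adjusted over the list alone (adjusted p = 0.298 with an estimated correlation). Of 37 middle genes 21 rose, with SPR28 at 2.53, and 1 fell, and 25 rose and 1 fell adjusted over the list alone; this list call held, with adjusted p = 0.0261 with an estimated correlation. Of 19 spore wall genes 11 rose, with CDA2 at 2.68 and DTR1 at 2.06, and 12 rose and 1 fell adjusted over the list alone (adjusted p = 0.0643 with an estimated correlation). All 33 proteasome genes rose adjusted over the list alone, 17 over all genes, with RPN13 at 1.08 and RPN12 at 1.03 (adjusted p = 0.298 with an estimated correlation). Of 28 chaperone genes 12 rose, with SSA3 at 1.68 and HSC82 at 1.38, and 16 did adjusted over the list alone (adjusted p = 0.298 with an estimated correlation). In the monopolin list 3 rose, MAM1 (2.52), SPO13 (1.05) and CSM1 (0.74), and 4 did adjusted over the list alone (adjusted p = 0.298 with an estimated correlation). Of 34 replication genes 11 fell, with PRI2 at -1.13 and POL12 at -1.08, and 14 fell and 1 rose adjusted over the list alone (adjusted p = 0.402 with an estimated correlation). Of 10 histone genes 4 fell, HTA2 (-1.20) and HHT1 (-0.97) among them, and 1 rose, the variant HTZ1 (1.14), and 8 fell and 1 rose adjusted over the list alone (adjusted p = 0.440 with an estimated correlation). In the cyclin list 2 of 10 fell, PCL2 (-1.65) and CTS1, on both counts. In the kinetochore list CTF19 (-1.08), which overlaps a neighbouring gene with the counted strand unknown, and HSK3 (-0.63) fell and SPC19 (0.70) rose, with the same counts adjusted over the list alone. GPA1, the pheromone response G protein, fell (-0.68), with 0 genes of its list adjusted over the list alone. RPP1A (0.79) and RPL15B (0.63) rose and IMP4, of ribosome biogenesis, fell (-1.24), with 0 genes adjusted over the list alone in both ribosome lists. As lists, both stood lower than other genes, by -0.32 and -0.75 in the median relative to all genes, with adjusted p = 0.742 and adjusted p = 0.614 with an estimated correlation. Without footprint 1.5 h replicate 1 the ribosomal protein value was -0.03 and the direction of its test turned (adjusted p = 0.760). ATG7 rose (0.72), and 1 autophagy gene rose and 2 fell adjusted over the list alone. SWI4, a G1 transcription factor among the long-isoform genes, fell (adjusted p = 0.0108) and HNT1 rose by 0.72, and 2 rose and 1 fell adjusted over the list alone. Among Rim4 targets GIP1 rose (1.65, adjusted p = 0.0167), and 2 did adjusted over the list alone. No glycolysis, gluconeogenesis, TCA cycle or respiratory gene passed on either count.

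In all, 237 footprint values rose and 229 fell, and the median gene changed by -0.07. Centring gave 331 up and 179 down, and quantile normalization 285 up and 216 down. The total of 466 was 111 and 798 without footprint 1.5 h replicate 1 or 2, and 68 and 52 without footprint 3 h replicate 1 or 2.

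In the main fit, translation efficiency did not change detectably between 1.5 and 3 h: 0 genes passed in limma, with 523 at an unadjusted p under 0.05. Voom on recovered reads also gave 0, while some genes passed with course libraries added or without a filter on mean RPKM. The median gene changed by -0.17. IRC18 (-1.65, adjusted p = 0.114), SMK1 (1.84, adjusted p = 0.263), SWI4 (adjusted p = 0.263) and NDT80 (0.70, adjusted p = 0.532) did not pass, nor did IME1 (0.60), NDC80 (-0.71) and CLB3 (-0.32). Adjusted over the list alone, 3 middle genes rose and 2 fell, 1 Rim4 target rose and 2 fell, 2 kinetochore genes, 1 cyclin gene and 1 long-isoform gene fell, and no gene of the other lists passed. As lists, early, middle, histone, replication, glycolysis, gluconeogenesis and TCA cycle genes stood higher and kinetochore, a-specific and ribosome biogenesis genes lower than other genes. Each of these list calls was lost, with the smallest adjusted p = 0.314 with an estimated correlation. The ribosome biogenesis median relative to all genes, -0.44, was 0.16 without footprint 1.5 h replicate 1. The count was 8 without mRNA 1.5 h replicate 1, 6 without footprint 1.5 h replicate 2, and 1 without footprint 1.5 h replicate 1 or footprint 3 h replicate 1. MCO10 and PET8 were the 2 genes whose mRNA rose (1.48 and 0.93) while footprints fell (-0.98 and -0.87), and none went the other way, where independent lists would give 6.95 and 1.91. Without footprint 3 h replicate 1 or 2 this count was 0, without footprint 1.5 h replicate 1 or either 6 h library of either assay it was 1, and without footprint 1.5 h replicate 2 it was 4. Both values rose in 81 genes (7.19 for independent lists) and fell in 33 (1.84), and the 2 changes correlated across genes with r = 0.46 and rho = 0.49.

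Between 3 and 6 h, when cells leave prophase and pass the meiotic divisions, mRNA of the middle and late sporulation genes rose steeply. GAT4, a GATA family factor of spore wall formation, rose by 9.53 (SE 0.484, limma, adjusted p = 1.58e-06), the transporter gene HXT10 by 9.40 (SE 0.473), SRD1 by 8.38 (SE 0.546), SPR2 by 8.33 (SE 0.441), SPS4 by 7.91 (SE 0.387) and PIR5 by 7.90 (SE 0.247, adjusted p = 2.21e-07). NDT80 rose by 3.54 (SE 0.218, adjusted p = 5.95e-06), while IME1 fell by 1.47 (SE 0.307, adjusted p = 0.00380). The largest falls were UTR5 (-4.02, SE 1.157), MTC7 (-3.08, SE 0.843), FYV5 (-2.91, SE 1.085), HUR1 (-2.83, SE 0.738), the chaperone gene SSA2 (-2.63, SE 0.752) and SCT1 (-2.61, SE 0.468). FYV5 and HUR1 overlap neighbouring genes, and the strand used in counting is not given in the sources used here. The median gene changed by -0.81, so the median of each list below is given relative to all genes.

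Of 37 middle genes 35 rose and 1 fell on both counts, over all genes and adjusted over the list alone, with SSP2 at 7.14 and PES4 at 5.39 (median 5.41 above all genes, adjusted p = 0.00268 with an estimated correlation). Of 19 spore wall genes 14 rose and 2 fell on both counts, with SPR1, a glucanase, at 5.97 and DTR1 at 5.67 (median 5.58, adjusted p = 0.0120 with an estimated correlation). All 6 Rim4 targets rose on both counts, SPS1 by 7.37, SPO20 by 5.65, GIP1 by 4.90, SSP1 by 4.22, CLB3 by 2.84 and AMA1 by 2.37 (median 5.37, adjusted p = 0.0120 with an estimated correlation). In the monopolin list CDC5, the polo kinase, rose by 3.30, the kinase HRR25 by 1.96 and MAM1 by 2.26, and on both counts 4 of 8 rose and 3 fell (median 1.58, adjusted p = 0.601 with an estimated correlation). Early genes fell, 33 of 36 over all genes and 35 adjusted over the list alone, with HOP1 at -1.85, ZIP1 at -1.67 and REC8, meiotic cohesin, at -1.75 (median -0.66, adjusted p = 0.689 with an estimated correlation). Of 34 replication genes 23 fell and 2 rose, with RFA2 at -1.86, MCM2 at -1.81 and ORC3 at 2.03, and 25 fell and 2 rose adjusted over the list alone (median -0.33, adjusted p = 0.689 with an estimated correlation). All 33 proteasome genes fell on both counts, PRE10 by 1.53 and RPT2 by 1.27 (median -0.45, adjusted p = 0.601 with an estimated correlation). Of 31 respiratory genes 29 fell on both counts, with COX12 at -1.59 and QCR2 at -1.56 (median -0.20, adjusted p = 0.601 with an estimated correlation). With centring, 17 early, 13 replication, 16 proteasome and 10 respiratory genes fell.

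Apart from the glycolysis list, the other lists held genes of both directions or lay near the median gene. Of 28 chaperone genes 18 fell, with HSP78 at -2.02 and HSP104 at -2.14, and 4 rose, with SSA3 at 1.93 (median -0.32). Of 29 autophagy genes 13 fell, with ATG7 at -1.62, and 6 rose, with ATG3 at 1.84 (median 0.06). Of 27 kinetochore genes 12 fell, with NNF1 at -1.59 and DAM1 at -1.48, and 2 rose (median 0.28), and with centring 5 fell and 5 rose. These 3 lists had the same counts adjusted over the list alone. Of 10 histone genes 7 fell on both counts, with HTA2 at -1.27 and HHT1 at -1.30 (median 0.03), and with centring 0 fell and 1 rose. Of 10 cyclin genes PCL2 (-1.97) and SIC1 (-1.40) fell and SWI5 (1.10) rose, and 2 fell adjusted over the list alone (median 0.06). Of 16 a-specific and haploid-specific genes 3 rose and 2 fell on both counts, with STE18 at 4.65 and STE4 at 1.51, both G protein subunits, and ASG7 at -1.80 (median 0.68, adjusted p = 0.601 with an estimated correlation). Its unadjusted median was -0.13 as deposited and 0.47 with centring. Of 137 ribosomal protein genes 3 rose, with RPL41A at 1.73 (-1.61 with course libraries added) and RPS28B at 0.96, and RPP1A fell by 0.65, and 0 passed adjusted over the list alone (median 1.19, adjusted p = 0.664 with an estimated correlation); with centring 39 rose and 0 fell. Of 63 ribosome biogenesis genes 14 fell, with SPB4 at -1.26, and 1 rose, and 0 passed adjusted over the list alone (median -0.02), whereas with centring 3 rose and 0 fell. Of 18 glycolysis genes 2 fell, with HXK1 at -1.52, and 1 did adjusted over the list alone (median 1.17, adjusted p = 0.689 with an estimated correlation), and with centring 2 rose and 1 fell. Of 15 gluconeogenesis genes 11 fell and 1 rose on both counts, with MLS1 at -1.58 and SFC1 at -1.44 (median -0.54). Of 15 TCA cycle genes 9 fell, with SDH1 at -1.81 and FUM1 at -1.40, and 9 fell and 1 rose adjusted over the list alone (median -0.01). Of the 5 long-isoform genes POR1 (-1.28), HNT1 (-1.07) and SWI4 (-1.04) fell and ORC1 (0.98, adjusted p = 0.0125) rose on both counts, and NDC80 did not pass (-0.23, adjusted p = 0.575; 0.38 with centring; 0.06 without mRNA 6 h replicate 2). Some members of this list may have been reported from these very samples, so it is no independent evidence of a direction.

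In all, 565 mRNAs rose and 2929 fell. With centring 878 rose and 825 fell (median -0.21), and with quantile normalization 786 rose and 1090 fell (median -0.24), so the excess of falls depends on the scaling.

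Footprints of many sporulation genes rose as well. ISC10, a meiosis-specific gene, rose by 10.59 (SE 0.663, limma, adjusted p = 3.1e-06), GAT4 by 9.76 (SE 0.395), HXT10 by 9.56 (SE 0.386), GIP1, a phosphatase subunit of spore formation, by 9.17 (SE 0.307), SPS1, a sporulation kinase, by 9.11 (SE 0.236) and SPR2 by 9.11 (SE 0.360). CLB3 (YDL155W) rose by 5.63 (SE 0.201, adjusted p = 7.02e-08) and NDT80 by 4.06 (SE 0.178). The largest falls were AIM26 (-4.44, SE 0.968), the cell wall genes SCW10 (-3.39, SE 0.501) and TOS6 (-3.24, SE 0.382), the splicing factor MSL1 (-3.16, SE 0.678), IRC19 (-3.11, SE 0.999) and COS6 (-2.85, SE 0.351), which has close paralogs. IME1 fell by 1.47 (SE 0.251).

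Of 37 middle genes 35 rose and 1 fell on both counts, with SPO20 at 8.09 and SPR6 at 7.92 (median 6.33 above all genes, adjusted p = 0.00587 with an estimated correlation). Of 19 spore wall genes 15 rose and 1 fell, with DTR1 at 6.77 and SPR1 at 6.52, and 16 rose and 1 fell adjusted over the list alone (median 6.29, adjusted p = 0.0208 with an estimated correlation). All 6 Rim4 targets rose on both counts, with SSP1 at 4.72 and AMA1 at 2.13 (median 7.30, adjusted p = 0.0218 with an estimated correlation). Early genes fell, 34 of 36 on both counts, with HOP1 at -1.80 (median -0.79, adjusted p = 0.535 with an estimated correlation). Of 34 replication genes 27 fell, with the clamp gene POL30 at -1.67 and RFA1 at -1.46, and 27 fell and 1 rose adjusted over the list alone (median -0.67, adjusted p = 0.535 with an estimated correlation). All 33 proteasome genes fell on both counts, with RPN12 at -1.30 and PRE10 at -1.23 (median -0.50, adjusted p = 0.535 with an estimated correlation). Of 31 respiratory genes 29 fell on both counts, with COX12 at -1.75 and ATP2 at -1.65 (median -0.76, adjusted p = 0.339 with an estimated correlation). Of 10 histone genes 8 fell and 1 rose on both counts, with HTA2 at -1.94 and HTB2 at -2.11 (median -0.89, adjusted p = 0.535 with an estimated correlation). Of 15 gluconeogenesis genes 11 fell, with MDH2 at -1.25, and 12 did adjusted over the list alone (median -0.56, adjusted p = 0.382 with an estimated correlation).

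In the monopolin list 4 rose, with CDC5 at 4.02, HRR25 at 2.57 and MAM1 at 2.60, and 2 fell, with SPO13 at -1.60, on both counts. Of 27 kinetochore genes 8 rose, with DAD3 at 2.49 and HSK3 at 1.76, and 11 fell, with CNN1 at -1.52 and DAM1 at -1.41, on both counts. Of 28 chaperone genes 8 rose, with SSA3 at 2.95 and HSP26 at 1.90, and 14 fell, with TPS2 at -1.64, and 9 rose and 14 fell adjusted over the list alone. With centring the kinetochore split was 10 up and 8 down and the chaperone split 11 up and 8 down. Of 29 autophagy genes 6 rose, with ATG4 at 1.71 and the receptor gene ATG40 at 2.72, and 14 fell on both counts. Of 10 cyclin genes 5 fell, with PCL1 at -2.13, and 1 rose, and 6 fell and 1 rose adjusted over the list alone. Of 16 a-specific and haploid-specific genes 4 rose and 1 fell on both counts, with STE18 at 4.90 and STE4 at 1.80 (median 0.64, adjusted p = 0.535 with an estimated correlation). Of 15 TCA cycle genes 9 fell and 2 rose on both counts, with IDH1 at -1.14 and KGD1 at 1.42. Of 137 ribosomal protein genes 6 rose, with RPS28B at 1.17, and 0 passed adjusted over the list alone (median 0.74, adjusted p = 0.734 with an estimated correlation). Of 63 ribosome biogenesis genes 4 rose, with DBP3 at 2.99, and 3 fell, with RPC10 at -1.11, and 4 rose and 1 fell adjusted over the list alone. Of 18 glycolysis genes 2 rose, with TDH2 at 1.21, and HXK1 fell (-0.86), and 1 fell adjusted over the list alone (median 1.18, adjusted p = 0.734 with an estimated correlation). Of the long-isoform genes NDC80 rose (1.92, SE 0.278, adjusted p = 0.000546), and ORC1 (-1.12, adjusted p = 0.00238), POR1 (-1.31) and HNT1 (-1.17) fell, on both counts, and SWI4 did not pass (0.22, adjusted p = 0.377).

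In all, 932 footprint values rose and 2422 fell, and the median gene changed by -0.45. With centring 1135 rose and 1701 fell (median -0.20), and with quantile normalization 1034 rose and 1913 fell (median -0.26).

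Translation efficiency between 3 and 6 h asks which genes gained or lost footprints beyond their mRNA. Some Rim4 targets were among the gains. GIP1 rose by 4.27 (SE 0.485, limma, adjusted p = 0.00788), CLB3 by 2.79 (SE 0.318, adjusted p = 0.00788) and SPO20, a membrane fusion protein, by 2.43 (SE 0.294, adjusted p = 0.0103). These are 3 of the 6 targets, and 4 rose adjusted over the list alone. All 6 targets are also in the middle list. SPS1 (1.74, adjusted p = 0.0629), SSP1 (0.50, adjusted p = 0.463) and AMA1 (-0.25, adjusted p = 0.729) did not pass. The list median stood 1.75 above all genes, and the list call (camera, adjusted p = 0.000527) was lost, with adjusted p = 0.219 with an estimated correlation. Other large rises were ISC10 (6.52, SE 1.049), TPH3 (6.05, SE 0.409), CNM1 (4.93, SE 0.862), IRC10 (4.26, SE 0.397) and AAD6 (4.27, SE 0.556), which has close paralogs. The largest falls were the Mediator subunit gene MED7 (-3.94, SE 0.421), CMG1 (-2.24, SE 0.347), the origin recognition subunits ORC3 (-2.18, SE 0.282) and ORC1 (-2.10, SE 0.345), HAP4 (-1.81, SE 0.277), an activator of respiratory genes, and PFA4 (-1.79, SE 0.306).

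Of 37 middle genes 8 rose, with ADY4, of the spindle pole body, at 3.59, and 19 did adjusted over the list alone (median 0.56 above all genes, adjusted p = 0.219 with an estimated correlation). In the spore wall list DIT1 rose (2.43), and 4 did adjusted over the list alone (adjusted p = 0.343 with an estimated correlation). In the chaperone list SSC1, mitochondrial Hsp70, rose (1.32), and 7 did adjusted over the list alone (adjusted p = 0.690 with an estimated correlation). In the replication list ORC3 and ORC1 fell on both counts (adjusted p = 0.635 with an estimated correlation). In the long-isoform list ORC1 fell, and 2 rose and 1 fell adjusted over the list alone. NDC80 stood at 2.15 (adjusted p = 0.0559) and SWI4 at 1.27 (adjusted p = 0.0875), which did not pass over all genes. No other list had a gene that passed over all genes, and adjusted over the list alone 2 kinetochore genes and 1 a-specific or haploid-specific gene rose. Histone, ribosomal protein and respiratory genes stood lower than others as lists, with adjusted p = 0.343, adjusted p = 0.753 and adjusted p = 0.458 with an estimated correlation. NDT80 (0.52, adjusted p = 0.343) and IME1 (0.00, adjusted p = 0.999) did not pass, and the sign for IME1 turned with the scaling, -0.36 with centring.

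In all, 68 genes rose and 11 fell, of which 3 are listed at 0 in all 4 footprint libraries of the 2 times, and the median gene changed by 0.33. With centring 21 rose and 11 fell, and with quantile normalization 22 rose and 17 fell. The total of 79 was 7 without footprint 6 h replicate 2, 12 and 160 without mRNA 6 h replicate 2 or 1, 21 and 33 without footprint 3 h replicate 1 or 2, 47 without footprint 6 h replicate 1 and 126 without footprint 1.5 h replicate 1.

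Some genes moved in opposite directions in mRNA and footprints. In 6 genes mRNA rose while footprints fell, among them MED7 (2.26 and -1.68), CMG1 (1.51 and -0.73), ORC1 (0.98 and -1.12), POP7 (1.09 and -0.90) and PEP4 (0.54 and -0.44), and 4 of the 6 had a lower translation efficiency. In 25 genes mRNA fell while footprints rose, among them TPO4, a polyamine exporter (-0.90 and 3.02), AAD3 (-1.72 and 1.93), MNE1 (-1.35 and 1.88), RCL1 (-1.45 and 1.15), CSE1, a nuclear export factor (-1.06 and 1.33), and GDT1 (-1.09 and 1.29). Independent lists would give 229 and 458 genes. Both values rose in 512 genes (88.3 for independent lists) and fell in 2070 (1189), and the changes correlated across genes with r = 0.81 and rho = 0.70. Relative to the median gene of each assay, 5 of the 6 and 18 of the 25 kept opposite signs. The excess of genes with lower mRNA and higher footprints turned with the scaling. With centring 2 genes went this way and 7 the other way, keeping 4 of the 31, and with quantile normalization 3 and 8, keeping 5. The total of 31 was 20 and 18 without footprint 3 h replicate 1 or 2, and 20 without footprint 6 h replicate 2.

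**Figure D3:**
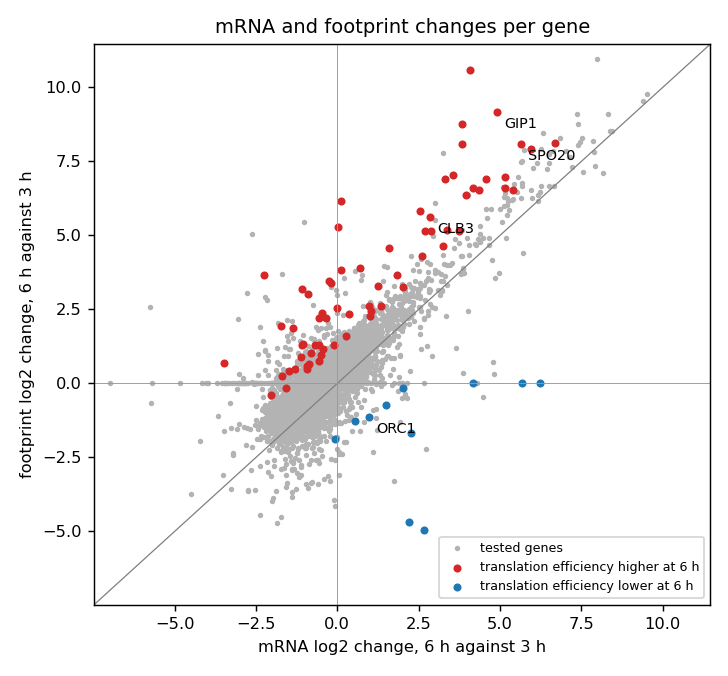
Log2 change of footprints (vertical axis) against log2 change of mRNA (horizontal axis) from 3 to 6 h for the 5967 tested genes. Genes with higher translation efficiency (68) are red and those with lower (11) blue; CLB3 lies at 2.84 in mRNA and 5.63 in footprints.

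The induction series asks which transcripts follow Ndt80. NDT80 mRNA was 45.0 to 79.8 RPKM in the 4 uninduced libraries and 1430 to 5626 in the 5 induced ones, a rise of 5.86 (SE 0.469, limma with hour as a linear term, adjusted p = 0.000442). The other genes that passed were GAL2, a galactose permease (6.50, SE 0.516, adjusted p = 0.000442), GAL7, of galactose breakdown (7.51, SE 0.869, adjusted p = 0.00726), and OPT1, an oligopeptide transporter (3.49, SE 0.316, adjusted p = 0.000987). The middle genes were higher with time after induction: relative to uninduced cells and all genes, their median was 0.04 at 5.75 h, 1.50 at 6 h, 4.77 at 6.5 h, 5.89 at 7 h and 6.36 at 7.75 h, against -0.76 to 0.61 in the uninduced libraries. The spore wall list reached 5.24, the Rim4 targets 6.35 and the early genes -2.38 at 7.75 h. The cyclin list stood at 0.59, 1.21 and 0.54 and the a-specific and haploid-specific list at 0.17, 0.76 and 0.90 at 6.5, 7 and 7.75 h, against -0.35 to 0.20 in the uninduced libraries. Over all genes 0 genes of any list passed in limma, where 613 of all genes had an unadjusted p under 0.05. Adjusted over the list alone, 22 of 37 middle genes rose, as did 3 of 19 spore wall genes, 2 of 8 monopolin genes and 1 of 6 Rim4 targets, and 2 of 15 gluconeogenesis genes rose and 6 fell, while no gene of the other lists passed. With an estimated correlation, adjusted p = 0.466 for the middle and spore wall lists, adjusted p = 0.615 for the Rim4 list, and adjusted p = 0.942 for the early, replication, proteasome and gluconeogenesis lists, which stood lower than other genes. ADY4 (3.38, adjusted p = 0.167), SPS4 (5.47, adjusted p = 0.177), CDC5 (3.30, adjusted p = 0.221) and CLB3 (1.26, adjusted p = 0.507) did not pass, nor did IME1 (-1.25, adjusted p = 0.499) and NDC80 (0.10, adjusted p = 0.867). The 4 genes became 106 without induced replicate 1, the 5.75 h library, and 8 with quantile normalization, and voom on recovered reads called 4.

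**Figure D4:**
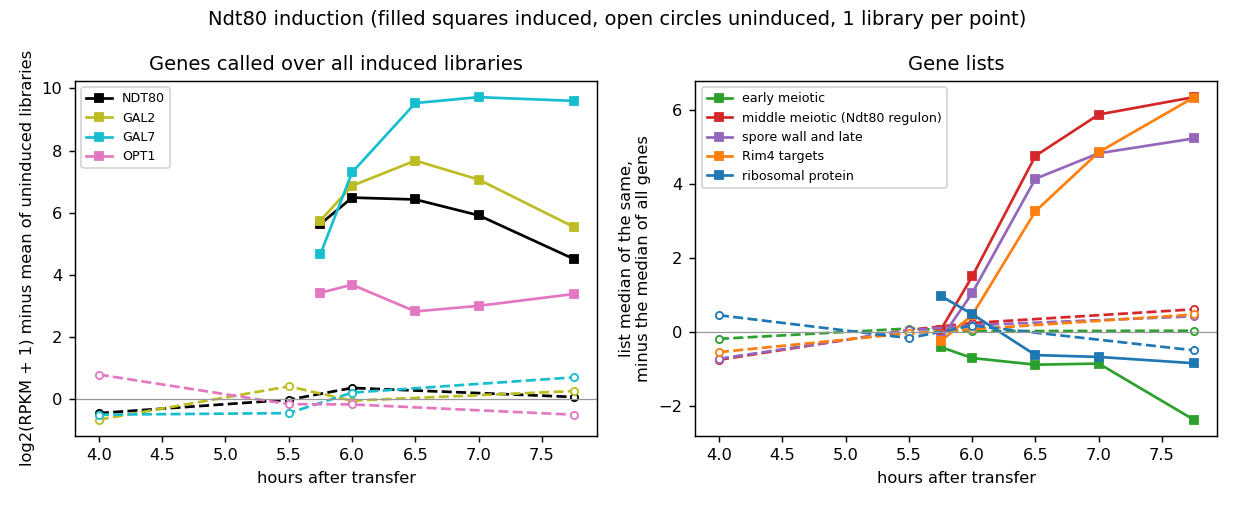
Left, log2 difference of NDT80, GAL2, GAL7 and OPT1 from the uninduced mean in the 4 uninduced and 5 induced libraries against hour. Right, median log2 difference of gene lists from the uninduced mean, relative to all genes; the middle list reaches 6.36 in the induced library at 7.75 h.

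With the 3 induced libraries from 6.5 h on set against the 4 uninduced ones, an alternative without an hour term that was fixed in advance, 637 genes rose and 2655 fell, and the median gene changed by -0.88. With centring 1096 rose and 1396 fell. Of the middle genes 34 rose and 2 fell, with SPS4 at 8.60 (SE 0.75), ADY4 at 4.75 (SE 0.32) and CDC5 at 4.59 (SE 0.40). Of spore wall genes 13 rose and 3 fell, and of Rim4 targets 5 of 6 rose, SPS1 by 6.29, SSP1 by 5.19, SPO20 by 4.03, GIP1 by 3.99 and CLB3 by 2.62, while AMA1 did not pass (1.13, adjusted p = 0.0548). Of 36 early genes 34 fell, with RIM4 at -2.05, UME6, a repressor of early genes, at -1.53 and IME1 at -1.92. Of 137 ribosomal protein genes 128 fell, as did 52 of 63 ribosome biogenesis genes, 21 of 34 replication genes and 15 of 33 proteasome genes. Among the 5931 genes tested in both series 2650 fell here, so the proteasome count lies near the share of all genes. Relative to all genes the medians of these 4 lists were -0.73, -0.76, -0.23 and -0.32. Of 10 cyclin genes 3 rose and 2 fell, and of 16 a-specific and haploid-specific genes 3 rose and 3 fell (medians 0.96 and 0.57 above all genes). With the hour term and all induced libraries, 0 ribosomal protein genes passed and their list stood 0.16 above all genes. The list's -0.73 was without the hour term and without the induced 5.75 and 6 h libraries, whose effects were not separated. Relative to all genes, this list was at 0.45 at 4 h and -0.50 at 7.75 h in uninduced libraries, and at 0.98 and 0.48 in the induced libraries of 5.75 and 6 h. NDC80 did not pass (0.13, adjusted p = 0.739). Of the 5931 genes tested in both series, 459 rose and 1877 fell both in this comparison and in wild-type mRNA between 3 and 6 h, where independent lists would give 60 and 1310, and 7 went opposite ways (563). The changes correlated across genes with r = 0.81. This overlap was counted on the deposited scale only, so the number of shared falls may depend on the scaling. In the comparison with the hour term, 3 of its 4 genes also rose in the wild type (0.380 for independent lists), with r = 0.74 and rho = 0.63. Uninduced and induced libraries share only the hours 6 and 7.75, and no library is a replicate of another at the same hour and state.

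Over the 7 tested contrasts and 20 lists, camera with a preset correlation called 69 of 140 list tests, 39 higher and 30 lower. With an estimated correlation 7 remained, all higher, the middle list in 3 h footprints and the middle, spore wall and Rim4 lists in mRNA and footprints between 3 and 6 h. The Rim4 targets are all in the middle list, so their calls are not separate from those of that list. The fry test, which asks whether the genes of a list move on balance in one direction and does not compare them with other genes, called 53.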

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

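Of the tests weighed here, those of a shift shared by genes with a similar mRNA rise, of counting noise, of the inducer acting on galactose genes and of other splits of the late induced libraries were chosen before their results were seen, and the others after. In 42 groups, each the 4 uninduced or the 5 induced libraries for 1 gene, 3 held a library far from the others. For replicates chance gives about 1 in 20 groups, but these libraries are different hours. A change with time can therefore also set a library apart. CDC5 had 201 RPKM in the induced library at 5.75 h, the first after induction, against 1447 to 3123 in the other 4. The gap took 0.719 of the range. NDC80 had 1168 RPKM in the uninduced library at 5.5 h, against 991.5 to 1011 in the other 3, with a gap of 0.880. RIM4 had 5367 RPKM in the uninduced library at 6 h, against 7990 to 8420, with a gap of 0.884.

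Among the named genes with opposite changes of mRNA and footprints between 3 and 6 h, the difference between the changes passed the interaction test in 8. These genes had been named for the largest such differences, so the choice favoured passing and the count is no separate evidence. It was -3.94 for MED7, -2.24 for CMG1, -2.10 for ORC1, 3.92 for TPO4, 3.65 for AAD3, 3.22 for MNE1, 2.38 for CSE1 and 2.38 for GDT1. These rest on 1 mRNA library at 3 h.

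The libraries labelled MATa/a 4.5 h did not match between assays. The mRNA library correlated across genes more with vegetative mRNA than with any sporulating state, by 0.20. A wrong sample or label for the mRNA and total RNA libraries would give this, but the value restates the observation itself and decides nothing. A swap with the vegetative libraries would leave acetate-use genes high in the library labelled vegetative, and the list median there was -7.67 against 0 h. A wrong sample or label and translational control in MATa/a cells cannot be told apart, since the list's translation efficiency, 6.06 above that of meiotic cells, compares libraries that may come from unlike cells.

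The translation efficiency of the 6 Rim4 targets had a median change of 2.09 between 3 and 6 h, against 0.33 for all genes. Of these, 3 passed, AMA1 stood at -0.25, and the list call was lost, with adjusted p = 0.219 with an estimated correlation. All 6 are also in the middle list, and they were not tested against the other middle genes. If the lone 3 h mRNA library of the parallel set made the change of the Rim4 targets, the course would lack it, but there the median was 2.02 relative to all genes. The lone column and the course bear the same replicate number, so they may share a culture. The course is therefore not shown to be an independent check of that sample. A shift shared by genes with a similar rise of mRNA is argued against by the percentile of 99.9 among 10000 random lists matched on mRNA change and level (random median 0.76, central range 0.10 to 1.50). With each 3 h footprint value at its upper 95% Poisson bound, the median rise was still 1.35, so counting noise alone would not give the rise. This value is not relative to all genes and lies inside the central range of the matched lists. Counting noise together with a shared shift is therefore not argued against. Release from Rim4 may be a hypothesis here, and it was not tested, because no library lacks Rim4 and the list may have been reported from these samples.

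GAL2 and GAL7 rose after Ndt80 induction. If the inducer acted on galactose genes directly, the other 5 galactose genes would be higher in the first induced library already. Their median was 1.16 above uninduced cells relative to all genes, while the middle list stood at 0.04. Not set against all genes, GAL10, GAL3 and GAL80 stood at 2.32, 1.91 and 1.28, but GAL1 at 0.47 and GCY1 at 0.13, near their uninduced values. The labels used here name no inducer, so a galactose-driven promoter is possible but was not tested further. As part of the meiotic programme, GAL2 would rise in the wild-type course, where it changed by -1.61 between 3 and 6 h, which argues against it, whereas GAL7 changed by 4.96, so for GAL7 both stay open. The galactose list had 7 genes and was chosen after GAL2 and GAL7 were seen.

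For the induction comparison, 100 of the 126 possible splits of the 9 libraries were drawn, and 4 of them, the real one included, gave at least its 4 genes. The share is under 0.05, but 3 other splits called at least as many, and not all splits were drawn. The libraries are different hours of an uninduced and an induced series and are not interchangeable. NDT80, among the 4 genes, was itself induced. The split test therefore cannot decide whether chance gave this count. The highest other split called 2383 genes, setting the 3 late induced libraries and the uninduced 4 h library against the rest, which points to a structure of the samples. With the induced libraries from 6.5 h on, 1 of 35 splits, the real one, gave 3292 genes and the highest other gave 0. That is the smallest share that 35 splits can give. No library is a replicate of another at the same hour and state. The share therefore cannot tell induction from differences of hour or culture.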

How the results depend on the processing

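Voom, leaving out the genes listed out of order, list tests on centred values and the overlap of the late induction comparison were chosen after the data were seen, and the other settings before. For the 262 named gene results, 5417 of 5949 values under alternatives kept direction and side of the threshold, 467 kept direction but no longer passed, 35 newly passed, 13 moved and 17 reversed. For 69 list calls, 1331 of 1402 values were the same, 68 no longer passed and 3 reversed. Unless a sentence says otherwise, the cause was not tested.

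The count of translation efficiency changes between 1.5 and 3 h was 0, and it was 1 with a pseudocount of 0.1, 11 without a filter on mean RPKM and 42 with course libraries added. Without 1 library it ranged from 0 to 8. The 79 genes between 3 and 6 h became 183 with a pseudocount of 5, 155 without a filter, 32 with median centring, 39 with quantile normalization, 10 with a replicate block, 1221 with course libraries added and 156 with voom on recovered reads. Without 1 library they ranged from 7 to 160.

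The 229 mRNAs between 1.5 and 3 h became 149 with centring, 124 without trend, 13 with a replicate block, 1147 with course libraries added, 19 with a separate fit per assay, where fewer libraries estimate the spread, and 692 with voom. Without 1 library they ranged from 61 to 309. The 466 footprint changes became 261 with at least a doubling or halving required, by construction, 180 with a replicate block and 1308 with course libraries added, and ranged from 52 to 798 without 1 library. Between 3 and 6 h the 3494 mRNAs became 1703 with centring and 1876 with quantile normalization, and ranged from 3037 to 3631 without 1 library. The 3354 footprint changes became 1923 with a doubling or halving, and ranged from 2492 to 3466 without 1 library.

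The 2 opposed genes between 1.5 and 3 h became 1 with a pseudocount of 0.1, centring or no trend, 0 with a doubling or halving, a replicate block or a separate fit per assay, 12 with course libraries added and 4 with voom, and ranged from 0 to 4 without 1 library. The 31 opposed genes between 3 and 6 h became 9 with centring (2 with higher and 7 with lower footprints, against 25 and 6) and 11 with quantile normalization (3 and 8), so that the larger direction turned and 4 and 5 of the 31 were kept. They became 9 with a doubling or halving, 17 with a replicate block and 108 with course libraries added, and ranged from 18 to 45 without 1 library. Differences between replicates 2 and 1 correlated across genes between groups at -0.11 to 0.24, and the labels do not say what samples with 1 number share across times, so the numbers were not taken to pair the samples.

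The 4 genes of the induction comparison became 8 with quantile normalization, 27 with the 6 h and 7.75 h libraries only and hour as a block, and 3292 with the induced libraries from 6.5 h on and no hour term, and ranged from 3 to 106 without 1 library. With those libraries 2336 genes were shared with wild-type mRNA in the same direction, counted on the deposited scale only. Of the 69 list calls 7 held with an estimated correlation. The median correlation of course and parallel changes, 0.68, was 0.74 with a pseudocount of 5, and 0.56 without replicate 2 and 0.65 without replicate 1.

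Some genes that did not pass changed sign. NDC80 footprints between 1.5 and 3 h (-0.08) were 0.04 with centring and 0.13 with quantile normalization, and ranged from -0.45 to 0.29 without 1 library (0.01 without 3 h replicate 1). NDC80 mRNA between 3 and 6 h (-0.23) was 0.38 with centring and ranged from -0.51 to 0.06. Translation efficiency of IME1 between 3 and 6 h (0.00) was -0.36 with centring, -0.21 with quantile normalization, -0.03 with course libraries added, -0.03 with voom, and ranged from -0.32 to 0.32 (-0.01 and -0.21 without footprint 3 h replicate 2 and 6 h replicate 1). That of CLB3 between 1.5 and 3 h (-0.32) was 0.04 with quantile normalization. RPL41A mRNA between 3 and 6 h (1.73), which passed, was -1.61 with course libraries added. In the induction comparison NDC80 (0.10) was -0.05 with the 6 h and 7.75 h libraries only, and AMA1 (0.22) ranged from -0.42 to 0.43, with -0.42 without uninduced replicate 4.

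Among lists, the ribosomal protein footprint median between 1.5 and 3 h, -0.32 relative to all genes, ranged from -0.69 to -0.03, where the test turned without footprint 1.5 h replicate 1. Translation efficiency of ribosome biogenesis genes (-0.44) ranged from -1.07 to 0.16, the latter without the same library. Ribosomal protein mRNA (-0.15) ranged from -0.58 to 0.31, the latter without mRNA 1.5 h replicate 1. Leaving out the lone 3 h mRNA library was not run for mRNA and translation efficiency, nor a separate fit per assay for translation efficiency, because neither gives a value. Depth limits genes with few footprint reads most, as in footprint 6 h replicate 2.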

Other observations

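All values here are of the course, which has 1 library per state, and no test was chosen for them. Relative to all genes and to 0 h, genes of the respiratory chain and ATP synthase had a median mRNA of -1.27 at 1.5 h and -1.86 at 10 h. Chaperone and stress genes stood at -2.07 at 1.5 h, and gluconeogenesis genes at -0.70 at 1.5 h and -1.72 at 10 h. Kinetochore genes stood 1.36 above 0 h at 1.5 h and 1.95 at 4.5 h, and monopolin genes 1.74 and 3.67.

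ORC1 had 198.5 RPKM of mRNA and 126.9 of footprints at 3 h, and 489.9 and 104.4 at 4.5 h. Footprints of CTS1 had 206 RPKM in growing cells and 6.42 at 0 h. RME1, chosen after its values were seen, had 19.9 RPKM of mRNA and 1126 of footprints in the libraries labelled MATa/a 4.5 h.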
